A study of Brassica oleracea var. italica with 48 samples.

How the data were processed

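RNA of roots and leaves of broccoli was extracted with a column kit and DNase and sequenced on a DNBseq instrument, per the labels. The submitters' processing notes name FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a and DESeq2, with no role or order. The genome build, the annotation and the counting tool are not given in the sources used here. The authors deposited 1 table of TPM, a unit that scales reads per length to a fixed total, which holds a value for each of 60586 features in each of 48 libraries and sums to 1000000 in every library, so each value is relative to the rest of its library. Of the feature IDs 54766 had the form Bo, digit, g and number, 4459 the form Bo, number, s and number, and 1361 began with ENSRNA. At 0 in every library were 12686 features. The table of gene names used here held 53125 genes and shared 0 IDs with the deposited table. HAK5, the lists of genes fixed before the data were examined and the markers of green tissue and root were therefore not analysed here.

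TPM does not keep the depth of a library. Each value is a number of reads divided by a length and by a factor of the library, so the values of a feature are whole multiples of a common step, and the smallest whole solution was taken as its reads. Whole reads were found for all 44911 features above 0 in 2 or more libraries, and 100% of their nonzero values lay within 0.05 reads of a whole number (largest deviation 0.000976). On simulated data the reads of 5901 of 5908 features (99.9%) were found exactly. The lengths found with them were multiples of 3 for 99.8% of the Bo features, with a median of 954 bases, and are called coding lengths. Median depth was 19.2 for root and 19.4 for leaf libraries, in units of 1000000 reads. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 5.40, root control b and c of day 1).

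The design fixed before the data were examined assumed counts and a count model. As the authors deposited TPM, the main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, on log2(TPM + 1). Fold changes are on that scale, which understates the change of features with few TPM. Features with at least 1 TPM in at least 4 libraries of the fit were tested, 29422 in roots, 25098 in leaves and 31520 in the fit of both tissues. Each tissue was fitted over its 24 libraries with a term per group of day and treatment, and the differences between tissues over all 48. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say that replicates were separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Tested on simulated data for roots on day 1, with 29263 features, the procedure called 67% of 100 features changed by a fold of 2, 97% of 100 changed by a fold of 4 and 0.0310% of the unchanged. For leaves on day 1 the shares were 74%, 95% and 0.0162%. The changed features were drawn among those with a mean of at least 100 reads. Each feature was simulated independently, without shifts that the features of a library share.

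Features were named by a rule fixed before the data were examined. Without gene names, it takes by ID up to 2 rises and 2 falls of largest log2 fold change per comparison, among called features with no overlap between the 4 and 4 libraries and a mean of at least 1. For the differences of effects, overlap was allowed. The sets of features called in a comparison were tested in the libraries of other comparisons with limma's camera (56 tests, adjusted together), with a preset correlation of 0.01 and with an estimated one, and the report gives the latter. No library is shared between the 6 comparisons of starvation and control. The table was read and its reads recovered in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

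Alternatives planned before the data were examined were no filter, a log2 fold change of at least 1, only the groups of the contrast, the replicate letter as a block and leaving out each library. Chosen after seeing the data were a pseudocount of 0.1, rescaling by medians of ratios, voom on the recovered reads, limma array weights, removal of each library's trend with coding length, leaving out 5 libraries with an array weight under 0.2, and, for controls between days, the block with only the groups of the contrast. The set tests, with their alternatives, were also added after seeing the data. An adjusted p given in the report for an alternative is the highest over the settings of that result unless a range or another p stands beside it. Planned count tools were not run, and the recovered reads were tested with voom only.

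Replicate letters were checked as pairs by correlating the deviations from the group means of starved and control libraries of the same letter. Only on day 3 in leaves were all 4 correlations over 0.1 (0.215 to 0.696), with 2 of 4 libraries correlating best with their own letter. The letters were taken as pairs there, from the data and not from the labels, before the calls of the fits were compared. The check cannot tell pairing from libraries that stand apart. The deviation of library a from the tissue mean had a Spearman rho with coding length of -0.576 in controls and -0.495 in starved leaves that day. A library that stands apart shifts its group mean, so the deviations of b, c and d can then correlate without pairing. The main fit and the splits did not use the letters.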

Results

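Broccoli (Brassica oleracea var. italica) is a vegetable crop of the cabbage family, and the plants studied here were wild type. Seedlings spent 6 days on MS plates and 7 days in hydroponic culture with 2 mM K2SO4, under 16 h of light and 8 h of dark. Part of the plants then went into a medium without potassium, the main inorganic cation of plant cells, and the rest served as controls. RNA of roots and leaves was sequenced on days 1, 3 and 6 to follow the response of each tissue to the loss of potassium, which gave 12 groups of 4 libraries, lettered a to d, and 48 libraries in all. The whole reads behind the deposited TPM values numbered 13819010 in the shallowest and 19735733 in the deepest root library, and 18350942 and 20160203 in the corresponding leaf libraries. The 10 most abundant features held 14.43 to 21.52% of the TPM of a leaf library and 2.66 to 5.90% of that of a root library. The series names the potassium transporter HAK5 and genes of salicylic acid synthesis. Of the 60586 feature IDs, 0 matched the gene table used here, so these genes, other gene lists and tissue markers were not analysed here, and features are given by ID. The features named for a comparison of starved with control plants, or of controls between days, are ones for which the 4 libraries of one group lay all above or all below the 4 of the other.

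In 5 libraries the estimated quality (limma array weight) was under 0.2: root control a and leaf control b of day 1, leaf starved d of day 1, leaf control a of day 3 and root starved d of day 3. In each of them features of short coding length stood higher than in the tissue mean. This was not particular to the 5. The Spearman rho of deviation and coding length was also negative in other libraries, among them leaf starved a of day 3 (-0.495) and root controls a and c of day 6 (-0.323 and -0.370). Without the 5 libraries limma called 2454 features in roots on day 1, 2533 on day 3 and 6205 on day 6, against 2472, 2263 and 4589 with all libraries, and in leaves 0, 2 and 2787.

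**Figure D1:**
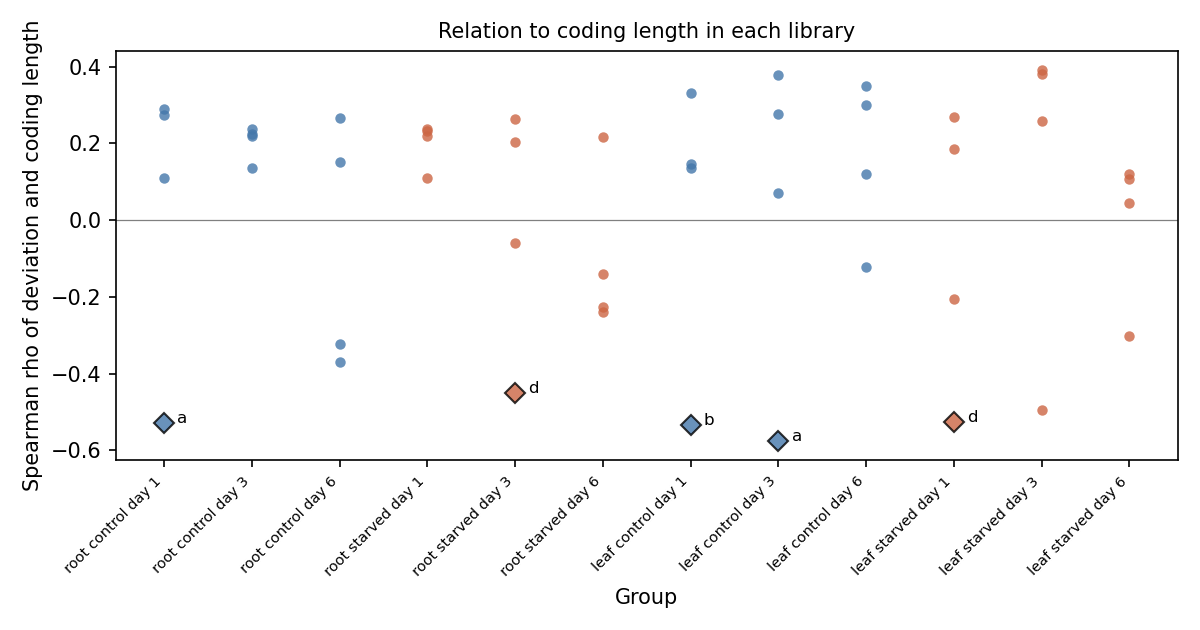
Spearman rho between coding length and each library's deviation from its tissue mean over features (vertical axis), by group (horizontal axis). Each point is a library, blue for control and orange for starved, and the 5 diamonds, marked by their letter, are libraries with an array weight under 0.2, whose rho lay between -0.576 and -0.450. Leaf starved a of day 3, not among the 5, lay at -0.495.

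One day after transfer, 1222 features had risen and 1250 had fallen in starved roots. Bo7g115930 stood at 0.857 ± 0.363 TPM in control roots and at 32.0 ± 5.02 TPM in starved roots (SD, n = 4 each), a log2 fold change of 4.16 (limma, SE 0.28, adjusted p = 7.18e-09). Bo5g065860 was at 0.217 ± 0.102 TPM in controls and 13.8 ± 5.70 TPM in starved roots, and its fold change was 3.54 (limma, SE 0.31, adjusted p = 2.15e-07). Bo8g082380, at 210 ± 39.2 TPM in controls and 12.2 ± 7.82 TPM in starved roots, fell by 4.36 on the log2 scale (limma, SE 0.62, adjusted p = 7.01e-05). Bo3g033000 went from 137 ± 44.0 to 6.93 ± 2.55 TPM and fell by 4.11 (limma, SE 0.43, adjusted p = 1.81e-06). Among the rises, 190 (15.5%) had a control mean under 1 TPM, against 5.83% of the 29422 features tested. Such a feature has little room to fall, and 12 (0.96%) of the falls had so low a control. This share and those given below therefore follow in part from the selection. The summed TPM of the rises was 39482 ± 2275 in controls and 81432 ± 5948 in starved roots, and that of the falls was 134773 ± 17302 and 70473 ± 3272. These sums and those given below come from the libraries that chose the features, so their direction was fixed in advance. The median coding length was 1062 bases for the rises and 789 bases for the falls, and 987 and 951 bases without the 5 libraries of low estimated quality. Rescaling by medians of ratios moved the median fold change of all features by -0.10 and gave 1064 rises and 1550 falls. The 2472 calls became 1348 (648 rises, 700 falls) with only the 8 libraries fitted and 7179 (3471 and 3708) with array weights, and 809 of them had a log2 fold change of at least 1 in either direction.

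**Figure D2:**
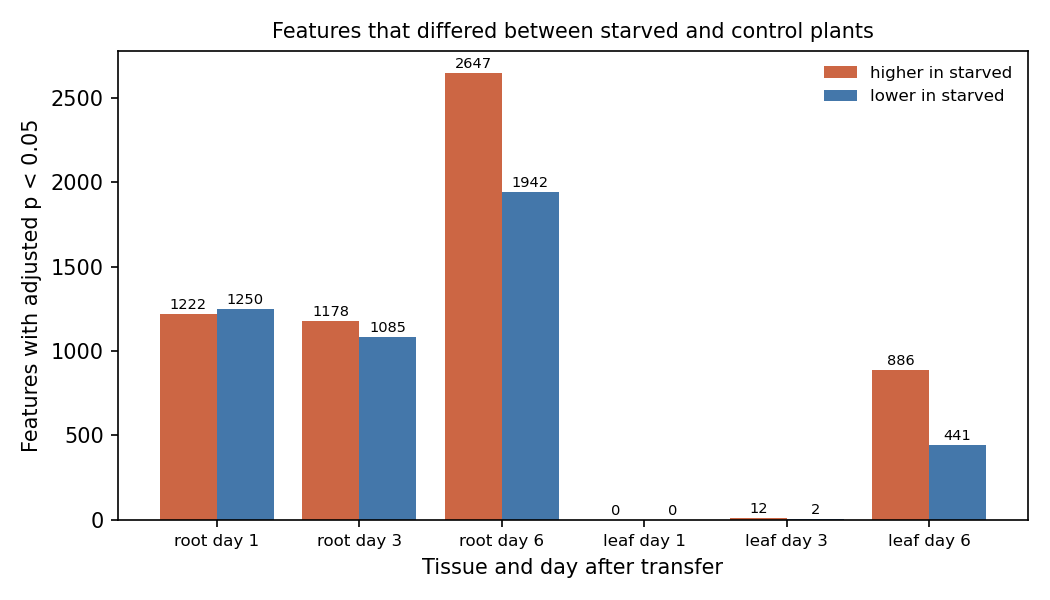
Number of features (vertical axis) with a limma adjusted p under 0.05 in starved against control plants, for each tissue and day (horizontal axis). Orange bars count features higher in starved plants and blue bars those lower. Root bars lie between 1085 and 2647, and the leaf bars are at 0 on day 1, at 12 and 2 on day 3 and at 886 and 441 on day 6.

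On day 3, 1178 features were higher and 1085 lower in starved roots. Bo1g021930 rose from 3.41 ± 1.21 to 189 ± 89.2 TPM (SD, n = 4 each), a log2 fold change of 5.37 (limma, SE 0.49, adjusted p = 2.07e-07). Bo9g002210 was listed at 0 in all 12 control root libraries. Its starved libraries a to d held 16.1, 16.1, 57.3 and 23.8 TPM on day 3, and the limma adjusted p was 8.87e-06. Bo3g033000 fell again, from 152 ± 38.6 to 6.45 ± 3.36 TPM. Bo4g002350 went from 15.8 ± 3.17 to 0.697 ± 0.355 TPM and fell by 3.31 (limma, SE 0.21, adjusted p = 2.65e-09). Features with a control mean under 1 TPM made up 208 (17.7%) of the rises and 5.11% of all tested. Rises had a median coding length of 813 bases and falls of 1068 bases, and 936 and 1017 bases without the 5 libraries of low estimated quality. The count of 2263 dropped to 1455 without control library d, to 1501 without starved library a and to 1428 with only the 8 libraries fitted, and was 5156 with array weights. A log2 fold change of at least 1 was found for 766 of the 2263.

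By day 6 the number of features that differed in starved roots was 4589, of which 2647 had risen and 1942 had fallen. Bo8g076240 stood at 1.51 ± 0.196 TPM in controls and 98.2 ± 36.5 TPM in starved roots (SD, n = 4 each), a log2 fold change of 5.22 (limma, SE 0.30, adjusted p = 1.84e-10). Bo1g021930 remained far above controls, at 148 ± 68.0 against 3.18 ± 0.432 TPM. Bo9g005670 went from 105 ± 15.2 to 5.04 ± 1.81 TPM and fell by 4.18 (limma, SE 0.26, adjusted p = 4.03e-10). Bo8g037940 went from 60.303 ± 5.62 to 3.75 ± 1.76 TPM and fell by 3.76 (limma, SE 0.26, adjusted p = 2.01e-09). A control mean under 1 TPM was found for 472 (17.8%) of the rises and 7.49% of all features. The 2647 rises together held 61047 ± 967 TPM in controls and 124365 ± 9657 TPM in starved roots, and the 1942 falls held 143847 ± 3785 and 78981 ± 4699 TPM. Medians of coding length were 933 bases for rises and 948 bases for falls. With array weights 7975 features were called (5268 rises, 2707 falls), and 1716 of the 4589 had a log2 fold change of at least 1.

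Many of the features called in roots were shared between days. In total 392 features were higher on all 3 days, with median log2 fold changes of 1.09, 1.03 and 1.40, and 340 were lower on all 3 days, with medians of -0.98, -1.01 and -1.15. Days 1 and 6 shared 729 rises, against 110 expected of independent lists, and 555 falls, against 82.5 expected. Days 3 and 6 shared 809 rises (106 expected) and 610 falls (71.6 expected). Of the 6350 features called on any day, 88 were higher on one day and lower on another. The features that rose on day 3 had a median log2 fold change of 0.82 on day 6, where 1109 of 1178 were higher (limma camera with an estimated correlation, adjusted p = 3.11e-05). Those that fell on day 3 had a median of -0.63 on day 6, with 953 of 1085 lower (limma camera with an estimated correlation, adjusted p = 0.00403). The day 1 rises and falls had medians of 0.71 and -0.41 on day 6 (limma camera with an estimated correlation, adjusted p = 0.00288 and 0.0124). For the day 1 falls that limma adjusted p on day 6 ranged from 0.0109 to 0.238 over the other settings, and passed 0.05 after rescaling by medians of ratios and with the coding length trend removed. Across the 29422 features, which are not independent replicates, the fold changes of days 3 and 6 had a Pearson r of 0.615 and a Spearman rho of 0.421. The values for days 1 and 3 were 0.410 and 0.123.

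The effect of starvation itself differed between days 1 and 6 in roots for 1192 features. The log2 fold change was more positive on day 6 for 747 and more negative for 445. Of the 747, 598 were called as rises on day 6, and of the 445, 332 were called as falls. Array weights called 4205 features in this test. Bo6g094710 changed sides. It stood at 47.7 ± 19.7 TPM in controls and 9.37 ± 8.73 TPM in starved roots on day 1, and at 9.10 ± 3.11 and 191 ± 14.5 TPM on day 6 (SD, n = 4 each). The difference of its log2 fold changes was 6.76 (limma, SE 0.77, adjusted p = 4.27e-05). Bo8g076240, at 5.80 ± 2.66 TPM in control and 7.69 ± 3.06 TPM in starved roots on day 1, gave a difference of 4.86 (limma, SE 0.42, adjusted p = 2.27e-06). In the other direction, Bo8g038180 rose from 13.1 ± 2.80 to 60.7 ± 23.7 TPM on day 1 and fell from 16.1 ± 4.33 to 6.89 ± 1.54 TPM on day 6, a difference of -3.15 (limma, SE 0.47, adjusted p = 0.000328). Bo8g068450 had 14.0 ± 22.4 and 60.9 ± 28.97 TPM on day 1 and 18.4 ± 15.5 and 9.33 ± 3.41 TPM on day 6. Its difference of -3.68 lay at the threshold (limma, SE 1.05, adjusted p = 0.0494) and was lost without each single library other than control a and starved b of day 1 and control b of day 6 (limma, adjusted p from 0.0572 to 0.114), and under 6 other settings (0.0506 to 0.0877).

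**Figure D3:**
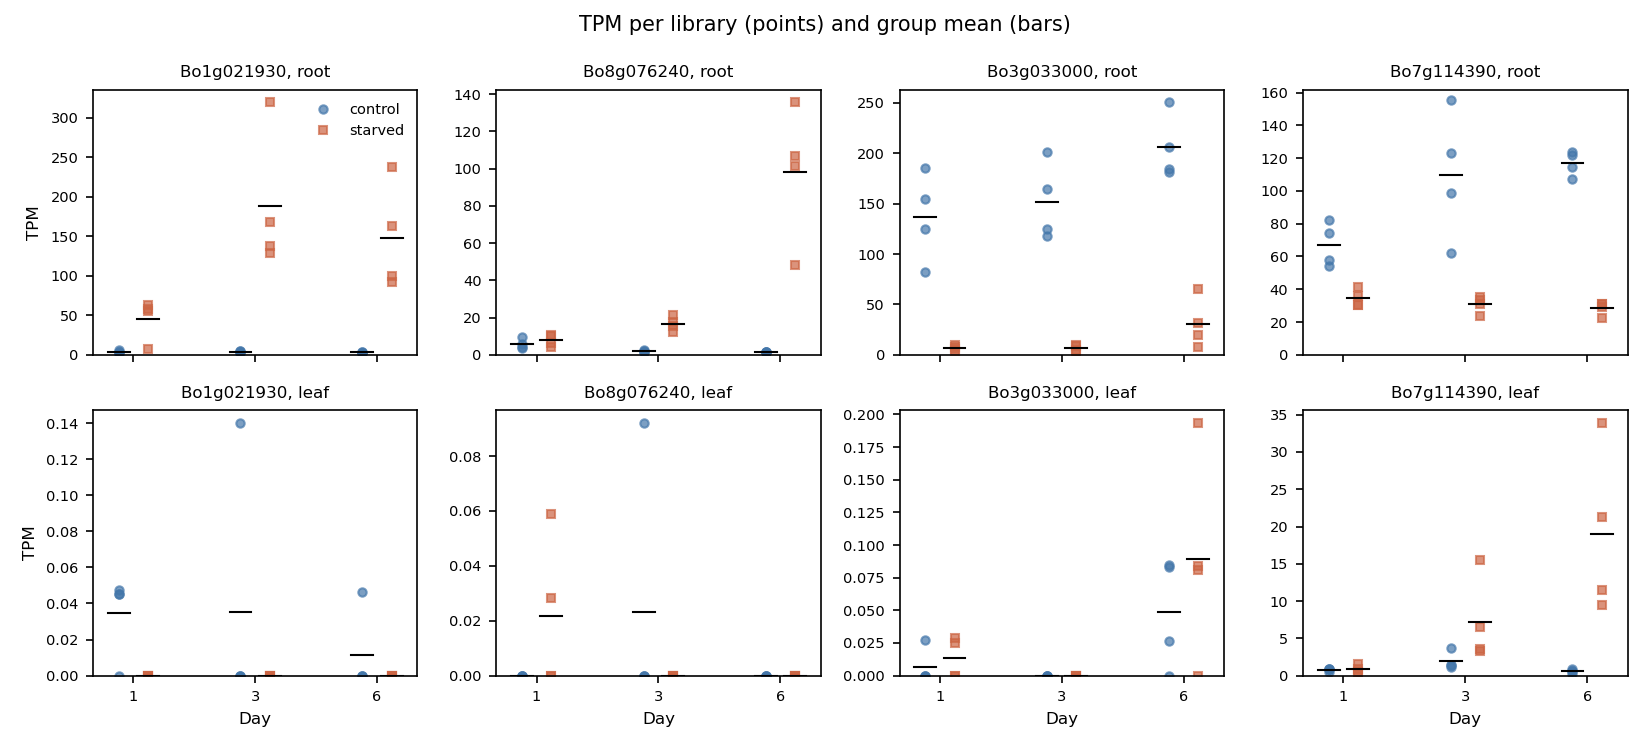
TPM (vertical axes, each with its own range from 0) of 4 features in each library, by day (horizontal axes), in roots (top) and leaves (bottom). Circles are control and squares starved libraries, and bars are group means. In starved roots on day 6 Bo8g076240 averaged 98.2 TPM against 1.51 TPM in controls, and Bo7g114390 was lower in starved roots (28.3 against 117 TPM) but higher in starved leaves (19.03 against 0.575 TPM).

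In leaves 1 day after transfer, limma called 0 of 25098 features. An unadjusted p under 0.05 was found for 627, which is fewer than the share of 0.05 of all features that no change would give. Voom on the recovered reads also called 0, and limma with array weights called 1. On data simulated for this comparison, 74% of 100 features changed by a fold of 2 and 95% of 100 changed by a fold of 4 were called, among 24857 tested. The changed features had a mean of at least 100 reads, and no library was simulated to stand apart. In the real data control b and starved d of this day were among the 5 libraries of low estimated quality. The shares are therefore no measure of the power of the real comparison. Bo6g028090, named by the comparison of both tissues below, had 1.12 to 13.5 TPM in the 4 control leaf libraries and 45.4 to 583 TPM in the 4 starved ones, and did not pass in leaves alone (limma, log2 fold change 5.05, adjusted p = 0.873).

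By day 3, 12 features had risen and 2 had fallen in starved leaves. Bo7g098860 went from 2.66 ± 2.02 to 15.1 ± 8.13 TPM (SD, n = 4 each), a log2 fold change of 2.13 (limma, SE 0.35, adjusted p = 0.0226). Bo3g163960 went from 1.00 ± 0.260 to 5.12 ± 1.21 TPM and had a fold change of 1.60 (limma, SE 0.20, adjusted p = 0.00185). Bo4g165150, at 480 ± 87.1 and 146 ± 68.1 TPM, fell by 1.81 (limma, SE 0.27, adjusted p = 0.0105), and Bo8g064850, at 25.3 ± 3.13 and 9.95 ± 3.85 TPM, fell by 1.32 (limma, SE 0.24, adjusted p = 0.0335). In control leaves both were lower on day 6 than on day 1, at 148 ± 37.3 against 947 ± 197 TPM and at 10.42 ± 2.10 against 54.9 ± 8.66 TPM. On day 6 the log2 fold changes of Bo7g098860 and Bo3g163960 were 3.24 and 1.40 (limma, adjusted p = 8.03e-06 and 0.000170), and those of the 2 falls were -0.35 and 0.20 (limma, adjusted p = 0.571 and 0.729). Chance was not excluded for the 14 calls, as 2 of the 35 splits of the 8 libraries, the real one included, gave as many. With the replicate letter as a block, 42 features were called, 40 higher and 2 lower, and Bo8g064850 had an adjusted p of 0.0582 in limma. The 14 calls became 2 without control library a or b, 1 without control d, 71 without starved library a, 3 without b, 2 without c and 6 without d, and 0 with the 8 libraries fitted alone. They numbered 2 with no filter or without the 5 libraries of low estimated quality, 1 with a pseudocount of 0.1, 33 with the coding length trend removed and 347 with array weights. In limma Bo7g098860 had adjusted p-values of 0.0677 to 0.127 without control a, b or d or starved b or c, Bo4g165150 of 0.0657 and 0.0561 without control d and starved c, and Bo8g064850 of 0.0639 to 0.143 without any control or starved c or d. Under other settings Bo7g098860 had 0.0539 with no filter and up to 0.218 in the fit of the 8 libraries, Bo8g064850 had 0.0582 to 0.152 and Bo4g165150 had 0.117 in that fit. Bo3g163960 had 0.0574 to 0.172 in the fit of the 8 libraries, with voom and with a pseudocount of 0.1.

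On day 6, 886 features had risen and 441 had fallen in starved leaves. Bo7g087150 stood at 1.67 ± 1.07 TPM in controls and 29.6 ± 11.5 TPM in starved leaves (SD, n = 4 each), a log2 fold change of 3.53 (limma, SE 0.48, adjusted p = 9.56e-05). Bo7g114390 was at 0.575 ± 0.267 and 19.03 ± 11.2 TPM, with a fold change of 3.52 (limma, SE 0.38, adjusted p = 7.81e-06). Bo5g021810 went from 9.07 ± 3.38 to 0.746 ± 0.624 TPM and fell by 2.51 (limma, SE 0.39, adjusted p = 0.000365). Bo5g113720 went from 8.21 ± 3.63 to 0.647 ± 0.419 TPM and fell by 2.41 (limma, SE 0.38, adjusted p = 0.000396). Both also fell in starved roots on day 6, from 24.2 ± 6.61 to 3.46 ± 3.35 TPM and from 11.6 ± 4.52 to 1.06 ± 1.10 TPM. Of the rises, 193 (21.8%) had a control mean under 1 TPM, against 6.79% of all features tested. Together the rises held 13732 ± 1505 TPM in controls and 32838 ± 2388 TPM in starved leaves. The median coding length was 780 bases for the rises and 954 bases for the falls. ENSRNA features took 0.0154 to 0.0206% of the reads in the control leaf libraries of day 6 and 0.0346 to 0.0840% in the starved ones. Control leaves had 0.0203 to 0.0569% on day 1 and 0.0324 to 0.0853% on day 3. The starved range of day 6 thus lay within that of the day 3 controls. The 1327 calls became 765 without starved library a, 813 without control b and 856 without control d. They numbered 2787 without the 5 libraries of low estimated quality, none of which belongs to day 6, 2154 after rescaling, 2192 with voom, 3208 with the coding length trend removed and 4079 with array weights, and 564 of the 1327 had a log2 fold change of at least 1. The excess of rises was small without those 5 libraries (1405 higher, 1382 lower), with array weights (2082 and 1997) and with only the 8 libraries fitted (736 and 659).

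The features that rose in leaves on day 6 had a median log2 fold change of 0.32 on day 3, with 766 of 886 higher (limma camera with an estimated correlation, adjusted p = 0.0124; 0.0109 with the replicate block). Those that fell on day 6 had a median of -0.18, with 372 of 441 lower (limma camera with an estimated correlation, adjusted p = 0.0191; 0.0595 with the replicate block and 0.0520 without the 5 libraries of low estimated quality). On day 1 the medians were 0.05 and -0.14, and neither set passed (limma camera with an estimated correlation, adjusted p = 0.1001 and 0.575). The test of the difference between days 6 and 1 called 142 features with a more positive effect on day 6 and 17 with a more negative one. Bo7g087150 differed by 3.54 (limma, SE 0.68, adjusted p = 0.0151) and Bo7g114390 by 3.51 (limma, SE 0.53, adjusted p = 0.00220). For Bo7g087150 the limma adjusted p was 0.0559 with a pseudocount of 0.1, 0.0615 without the 5 libraries of low estimated quality and 0.288 with voom. Bo8g045830 differed by -1.90 (limma, SE 0.36, adjusted p = 0.0138; 0.0508 with a pseudocount of 0.1 and 0.0875 with voom). It stood at 14.8 ± 4.67 TPM in control and 4.23 ± 1.58 TPM in starved leaves on day 6 (SD, n = 4 each). On day 1 it was at 0.602 ± 0.282 and 0.972 ± 0.320 TPM, with little room to fall. Its difference therefore restates in large part the effect on day 6, of -1.59. Bo1g115950, at 282 ± 61.7 and 97.3 ± 34.6 TPM on day 6, differed by -1.83 (limma, SE 0.33, adjusted p = 0.00725). The 159 calls became 62, 100, 87 and 98 without starved libraries a of day 6 and a, b and d of day 1, 78 without starved d of day 6, 82 and 87 without controls c and d of day 1, 73 without control b or d of day 6, and 338 without control a of day 6. Under other settings they numbered 82 with a pseudocount of 0.1, 95 without the 5 libraries of low estimated quality, 97 with voom, 249 with the replicate block, 253 after rescaling, 285 with the coding length trend removed and 862 with array weights.

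Root and leaf responses were compared directly on each day. The fit treated root and leaf libraries as separate samples. Whether those of the same letter came from the same plants is not given in the labels and was not checked. Of the features in the fit of both tissues, 23064 passed the filter in each tissue. A feature near 0 TPM in a tissue has an effect near 0 there, so its difference restates the effect in the other tissue. Such features are part of the counts below, and their number was not counted. On day 1 the effect was more positive in roots for 773 features and more negative for 706, and after rescaling by medians of ratios, which moved the median of all features by -0.19, the numbers were 567 and 917. The 1479 calls became 398 with voom, 820 with a pseudocount of 0.1 and 3313 with array weights, and 799 of them had a difference of at least 1 on the log2 scale. The balance also turned with only the 4 groups fitted, with voom, with array weights, with the coding length trend removed and without the 5 libraries of low estimated quality, and without root control a (588 and 649), leaf control a (587 and 611) or leaf starved d (562 and 661). Bo7g115930 differed by 4.08 (limma, SE 0.33, adjusted p = 1.96e-11) and Bo5g065860, listed at 0 in all leaf libraries of day 1, by 3.54 (limma, SE 0.32, adjusted p = 3.07e-10). Bo6g028090, at 0.705 ± 0.712 TPM in control and 0.486 ± 0.218 TPM in starved roots (SD, n = 4 each), differed by -5.17 (limma, SE 1.28, adjusted p = 0.010). Bo8g082380, at 0.446 TPM on average in both leaf groups, differed by -4.38 (limma, SE 0.66, adjusted p = 1.44e-05), against -4.36 in roots alone. With voom both of the latter had limma adjusted p-values past the threshold, 0.333 and 0.0586.

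On day 3, 691 features had a more positive and 834 a more negative effect in roots, and rescaling moved the median of all features by 0.10. The 1525 calls became 522 (227 more positive, 295 more negative) with voom, 976 with a pseudocount of 0.1, 989 with only the 4 groups fitted and 3812 with array weights, and 884 of them had a difference of at least 1 on the log2 scale. Bo1g021930, at 0.0350 TPM or less on average in each leaf group, differed by 5.42 (limma, SE 0.52, adjusted p = 5.25e-10), and Bo9g002210, listed at 0 in every leaf library of day 3, also passed (limma, adjusted p = 3.31e-07). Bo3g033000, listed at 0 in every leaf library of day 3, differed by its fall in roots alone, -4.45 (limma, SE 0.45, adjusted p = 2.41e-09; 0.0796 with voom). Bo7g114010 fell in roots from 53.8 ± 33.2 to 11.6 ± 8.78 TPM and stood at 1.60 ± 1.77 and 7.82 ± 9.58 TPM in leaves (SD, n = 4 each), a difference of -3.64 (limma, SE 0.71, adjusted p = 0.000699; 0.0782 when only the 4 groups were fitted).

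On day 6 the tissues differed for 4266 features, 2407 of them more positive in roots and 1859 more negative, a balance that turned to 1685 and 1858 with voom and to 2636 and 2788 with the coding length trend removed. With array weights 8236 differed, and 2352 of the 4266 did so by at least 1 on the log2 scale. Bo8g076240, listed at 0 in all leaf libraries of day 6, differed by 5.22 (limma, SE 0.31, adjusted p = 8.53e-16) and Bo1g021930 by 5.07 (limma, SE 0.52, adjusted p = 8.28e-10). Bo7g114390 moved in opposite directions. It fell in roots from 117 ± 7.55 to 28.3 ± 4.14 TPM and rose in leaves, a difference of -5.53 (limma, SE 0.44, adjusted p = 2.13e-12). Bo9g005670, at 1.48 ± 1.39 TPM in control and 2.35 ± 0.680 TPM in starved leaves, differed by -4.73 (limma, SE 0.38, adjusted p = 2.72e-12). Across the 23064 features tested in both tissues, which are not independent replicates, root and leaf fold changes of the same day had a Pearson r of -0.155, -0.115 and 0.0345 on days 1, 3 and 6. Between different days r lay between -0.0992 (root day 1, leaf day 6) and 0.148 (root day 3, leaf day 1), with 0.122 for root day 1 and leaf day 3. The same-day values alone therefore do not show opposed responses. Roots and leaves shared 86 rises on day 6 (49.0 expected of independent lists) and 70 falls (20.1 expected), 134 features fell in roots and rose in leaves (47.5 expected), and 39 rose in roots and fell in leaves (20.8 expected). None of the sets of root rises or falls passed in leaves on any day with an estimated correlation (limma camera, lowest adjusted p = 0.359), except that after rescaling the root falls of day 3 were higher in leaves on day 6 (limma camera, adjusted p = 0.0466).

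Control plants were also compared between days 6 and 1. In control roots 668 features were higher and 1171 lower on day 6, and 935 and 972 after rescaling by medians of ratios. The balance turned to 1327 and 1170 with the coding length trend removed and was 2775 and 13185 with array weights. Bo3g052490 went from 7.58 ± 2.24 to 60.11 ± 47.2 TPM (SD, n = 4 each), a log2 fold change of 2.55 (limma, SE 0.46, adjusted p = 0.00174). Bo9g177190 went from 27.99 ± 13.8 to 159 ± 40.5 TPM (limma, 2.54, SE 0.48, adjusted p = 0.00260). Bo7g106050 was at 32.1 ± 14.6 and 2.65 ± 1.56 TPM and fell by 3.17 (limma, SE 0.30, adjusted p = 2.38e-06). Bo9g066800 was at 63.7 ± 13.9 and 6.40 ± 2.48 TPM and fell by 3.16 (limma, SE 0.27, adjusted p = 7.10e-07). In starved roots on day 6 this last feature was at 62.3 ± 22.2 TPM. Chance was not excluded here, as 5 of the 35 splits of these 8 libraries, the real one included, gave at least 1839 calls. The numbers were 691 with only the 8 libraries fitted and 1170 with the replicate block added to that fit, and 514 of the 1839 had a log2 fold change of at least 1. The 1839 calls became 6024 without the 5 libraries of low estimated quality, 1 of which is control a of day 1. They numbered 3395 without that library alone, 1173 and 1051 without c and d of day 1, and 960 and 1205 without a and c of day 6.

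In control leaves 2387 features were higher and 1787 lower on day 6 than on day 1. This balance turned to 2640 and 2681 after rescaling, 2663 and 2696 with voom, 3381 and 3607 with the coding length trend removed, 2393 and 2682 without the 5 libraries of low estimated quality, and 1623 and 1659 without control library b of day 1. Bo8g045830 rose from 0.602 ± 0.282 to 14.8 ± 4.67 TPM (SD, n = 4 each), a log2 fold change of 3.26 (limma, SE 0.26, adjusted p = 8.64e-08). Bo00722s060 went from 16.4 ± 3.37 to 248 ± 254 TPM (limma, 3.19, SE 0.88, adjusted p = 0.0147), and missed the threshold without control library a or b of day 6 (limma, adjusted p = 0.0785 and 0.0526). Bo8g108830 was at 22.6 ± 7.79 and 0.642 ± 0.456 TPM and fell by 3.83 (limma, SE 0.45, adjusted p = 6.61e-06). Bo2g149980 went from 34.6 ± 15.3 to 2.21 ± 1.61 TPM and fell by 3.49 (limma, SE 0.47, adjusted p = 2.67e-05). Without control library a of day 6 the 4174 calls became 2593. They numbered 2751 with only the 8 libraries fitted, 1592 with the replicate block added to that fit, 6988 with the coding length trend removed and 7617 with array weights, and 1001 of them had a log2 fold change of at least 1.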

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

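The tests of coding length and of depth for the 5 libraries of low weight, the use of array weights to find these libraries, the removal of the length trend and the test of features called in both tissues were chosen after the result was seen. The other tests of this part were set before their own results.

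In groups of 4, a library far from its nearest neighbour was looked for in 60 groups of library values and 39 groups of named features, and chance gives about 5% of groups. Root control a of day 1 held 25913 features at 1 TPM or more (27785 to 28053 in the others), and its value for Bo8g082380 was 268 TPM (185 to 197). In leaf control a of day 3 the 10 most abundant features held 19.3% of the TPM (15.0 to 15.8%). ENSRNA features took 0.0300% of the reads in root starved d of day 3 (0.0176 to 0.0194%) and 0.126% in leaf starved d of day 1 (0.0320 to 0.0423%). The rho of the deviation from the tissue mean with coding length was 0.109 in root starved d of day 1 (0.219 to 0.237) and -0.495 in leaf starved a of day 3 (0.258 to 0.392). Bo7g098860 stood at 5.69 TPM in leaf control c of day 3 (1.39 to 1.85), Bo5g021810 at 4.01 TPM in leaf control b of day 6 (10.5 to 11.001), and Bo5g113720 at 1.27 TPM in leaf starved b of day 6 (0.4001 to 0.502).

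The first component took 33.0% of the variance in roots and 40.2% in leaves. On it the leaf libraries with an array weight under 0.2 scored 0.348 or more, against at most 0.210 in the other leaf libraries. Root control a of day 1 also stood apart (0.546), but root starved d of day 3 (0.348) did not. Root controls a and c of day 6 scored 0.353 and 0.341, and b and d -0.0182 and -0.00484, so this control group was split. By residual SD the 5 libraries stood apart, at 0.498 or more against at most 0.460 in the others. With the coding length trend removed, the median residual SD of the 5 libraries of low weight was 0.514, above the highest of the other 43, 0.412. A smooth trend with coding length as the whole cause was thereby excluded for the 5 as a set. For leaf control a of day 3 it was not, as its value of 0.41231 lay under that highest one, 0.412387. RNA carried over from the other tissue as the whole cause was also excluded for the set (0.566 against 0.461). Array weights themselves fall with residual spread, so the 5 were chosen for a high one. A part played by length may remain, as the loadings ranked with coding length with an absolute rho of at least 0.509 in both tissues. So may lower depth, as 5 of the 5 held fewer reads than every other library of their group. The gap was wide in root starved d of day 3 (13819010 reads, next 17497553). It was narrow in leaf control b of day 1 (18636634, 18815416) and leaf control a of day 3 (19118194, 19269558). Root starved b of day 1 held fewer reads (17770834) than root control a (17804694) at an array weight of 1.37. A wrong label stays open, as 1 of the 5 correlated best with its own group against 33 of the other 43, although their highest mean correlation with any group was 0.952 to 0.974, where the lowest of the others was 0.972, and some carry-over stays open, as 3 of the 5 had more of the other tissue's features than every other library of their group, at a share of at most 0.649%. No biological explanation was tested, as the 5 come from 5 groups.

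The effect of starvation differed by a test of the difference itself for 1192 features between days 6 and 1 in roots, for 159 in leaves, and between roots and leaves for 1479, 1525 and 4266 features on days 1, 3 and 6. The counts between tissues include features near 0 TPM in a tissue, for which the difference restates the effect in the other. How many these were was not counted. Between days 6 and 1 the log2 effects in roots differed by 4.86 for Bo8g076240, -2.08 for Bo9g005670, 6.76 for Bo6g094710, -3.68 for Bo8g068450 and -3.15 for Bo8g038180. In leaves they differed by 3.54 for Bo7g087150, 3.51 for Bo7g114390, -1.90 for Bo8g045830 and -1.83 for Bo1g115950. Root minus leaf on day 1 was 4.08 for Bo7g115930, 3.54 for Bo5g065860, -4.38 for Bo8g082380, -4.12 for Bo3g033000 and -5.17 for Bo6g028090. On day 3 it was 5.42 for Bo1g021930, -4.45 for Bo3g033000, -3.23 for Bo4g002350, -2.67 for Bo7g098860, -1.48 for Bo3g163960, 1.63 for Bo4g165150, 1.47 for Bo8g064850 and -3.64 for Bo7g114010. The fitted 4.67 for Bo9g002210 depends on the pseudocount, as its controls are listed at 0, and is no bound. On day 6 it was 5.22 for Bo8g076240, 5.07 for Bo1g021930, -4.73 for Bo9g005670, -3.82 for Bo8g037940, -3.73 for Bo7g087150 and -5.53 for Bo7g114390. Bo8g037940 averaged 0 and 0.0423 TPM in control and starved leaves on day 6. Bo3g033000 averaged 0.00690 and 0.0133 TPM on day 1, and Bo4g002350 0.134 and 0.0710 TPM on day 3. Their differences restate the effects in roots, of -3.76, -4.11 and -3.31.

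The features that fell in roots and rose in leaves on day 6 numbered 134, against 47.5 of independent lists, but the other classes were also above theirs (86 against 49.0 for shared rises, 70 against 20.1 for shared falls, 39 against 20.8 for rises in roots that fell in leaves). The excess may come from features called in both tissues whatever their direction, as the margins of these 329 features give 136.4 for the opposite class, with 95% of random pairings at 128 to 145. Expression level as the whole cause was excluded, since 10000 draws of features matched on it gave a mean of 65.3 and at most 94, and so was a trend with coding length as the whole cause, since with it removed 260 such features were found against 163 expected, a ratio of 1.59 ± 0.0988 (counting error), above the highest of the matched draws, 228, a comparison added after the ratio was seen. An opposite response of the same features stays open, as their median root minus leaf effect of -1.03 on day 3 decides nothing where each list kept its own direction on that day. Across the separate lists of root day 3 and leaf day 6 the opposite class held 140 features against 128 from the margins, above the upper end of 95% of random pairings, 133, and across root day 1 and leaf day 6 it held 87 against 82.4 (95% at 77 to 88), where features are not independent replicates.

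Other splits of the same libraries into groups of the same sizes were fitted to see whether chance can be excluded. In roots only the real split, 1 of 35, gave as many calls on each day. The real and highest other counts were 2472 and 6 on day 1, 2263 and 106 on day 3, and 4589 and 2 on day 6. A share of 1 of 35 is the lowest these splits can reach, and it was not corrected for the number of comparisons. A first rank therefore argues against chance but does not exclude it. In leaves the real split ranked first on day 6 (1 of 35 splits, 1327 against 568), but not on day 3, where 2 of 35 splits gave at least 14 calls. The larger gave 42, with control a, b and d beside starved a, which keeps both libraries of letters a and c together, and each remaining split, those that part all 4 pairs included, gave 2 or fewer. On day 1 all 35 splits gave the real value of 0. For the difference between days, 3 of 100 splits gave as many calls in roots (1192, highest other 3024) and 3 of 100 in leaves (159, highest other 540). These splits exchange starved and control libraries within a day and tissue, so they stand for no effect of starvation at all. They cannot tell whether chance is excluded for a difference between effects. The 540 keeps both real groupings with the sign of 1 day turned, and one root split of 3005 keeps the real grouping of day 6. For root minus leaf the splits with as many calls were 2 of 100 on day 1 (1479, highest other 6134), 1 of 100 on day 3 (1525, 1023) and 1 of 100 on day 6 (4266, 3009). These too decide nothing on a difference between tissues, as the splits of 1023 and 3009 keep the real grouping of the roots. The 6134 points to a structure of the samples on day 1. In control leaves between days 6 and 1 the real split ranked first (1 of 35, 4174 against 10). In control roots 5 of 35 splits gave at least 1839 calls, so chance is not excluded, and the 4 others, of 3419, 5271, 9201 and 9965 calls, all put control a of day 1 with controls a and c of day 6, which points to a structure of the samples.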

How the results depend on the processing

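Alternatives with another pseudocount, rescaling, voom, array weights, the length trend removed or the 5 low-weight libraries left out were chosen after seeing the data. No named feature or set of features called in the reported fits reversed its direction under an alternative, but the balance of rises and falls turned in some comparisons. It turned for root minus leaf on days 1 and 6 and in control roots and leaves between days, as the report gives. Root minus leaf on day 1 had 505 more positive and 552 more negative features with only the groups of the contrast, 142 and 256 with voom, 1520 and 1793 with array weights, 638 and 1131 with the length trend removed and 527 and 613 without the 5 libraries. Roots on day 1, with 1222 rises and 1250 falls, had 418 and 391 at a log2 fold change of at least 1, 1346 and 1267 with the block, and more rises without control b, c or d or starved d (1095 and 1053, 1434 and 1226, 965 and 913, 1028 and 933). Roots on day 3 had 1071 and 1105 with voom and 975 and 1119 without control b. Leaves on day 3 had 0 rises and 1 fall with the other pseudocount and 1 and 2 without starved b. The cause of each change was not tested, except that fitting only the groups of the contrast leaves fewer libraries and that a log2 fold change of at least 1 is stricter by construction. Counts below are those that moved by over 1.5 times. With a log2 fold change of at least 1 the calls were 809, 766 and 1716 in roots on days 1, 3 and 6, 564 in leaves on day 6, 799, 884 and 2352 for root minus leaf, and 514 and 1001 for control roots and leaves between days. Array weights gave 7179, 5156 and 7975 in roots, 1, 347 and 4079 in leaves, 4205 and 862 for the difference between days in roots and leaves, 3313, 3812 and 8236 for root minus leaf, and 15960 and 7617 in control roots and leaves. Removing the length trend gave 33 and 3208 in leaves on days 3 and 6, 285 for their difference between days and 6988 in control leaves. Rescaling gave 2154 in leaves on day 6 and 253 for their difference between days. Without a filter leaves on day 3 had 2 calls. Fitting only the groups of the contrast gave 1348 and 1428 in roots on days 1 and 3, 0 in leaves on day 3, 989 for root minus leaf on day 3, and 691 and 2751 in control roots and leaves. A pseudocount of 0.1 gave 1 in leaves on day 3, 82 for the leaf difference between days, and 820 and 976 for root minus leaf on days 1 and 3. With voom the counts were 2192 in leaves on day 6, 97 for their difference between days, and 398 and 522 for root minus leaf on days 1 and 3. Without the 5 libraries they were 2 and 2787 in leaves on days 3 and 6, 95 for their difference between days and 6024 in control roots.

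The replicate block gave 42 calls in leaves on day 3 and 249 for the leaf difference between days, and it moved no other count by over 1.5 times (2184 and 3921 in control roots and leaves). With the block and only the groups of the contrast together, added after seeing the data, control roots and leaves had 1170 and 1592 calls, against 691 and 2751 with those groups and no block. It ended the calls of Bo8g064850 in leaves on day 3 and Bo8g068450 for the root difference between days, and of 1 of 56 sets. Of 24 pairs of the same letter 14 correlated over 0.1 (-0.46 to 0.70) and 9 correlated best with their own letter.

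Leaving out each library in turn gave 1799 to 2660, 1455 to 2147 and 3592 to 4438 calls in roots on days 1, 3 and 6, and 0, 1 to 71 and 765 to 1324 in leaves. The difference between days had 861 to 1365 in roots and 62 to 338 in leaves, root minus leaf 1113 to 1664, 1102 to 1642 and 3639 to 4245, and control roots and leaves 960 to 3395 and 2593 to 4591. Of the calls of named features 516 remained and 28 were lost on leaving out a library. Over the 48 calls, voom, the other pseudocount and only the groups of the contrast lost 6 each, no filter and leaving out the 5 libraries 3 each, the block 2, rescaling and length removal 1 each, and array weights 0. Of the sets, rescaling ended 4 calls, all between days in roots (adjusted p in limma's camera 0.0802 to 0.238), and gave 1, length removal ended 2, leaving out the 5 libraries ended 1, and the other pseudocount 0. The count tools planned, with their other normalizations, and the alternatives for HAK5 and gene lists, were not run. Depth limits features of few reads, for which log2(TPM + 1) understates folds.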

Other observations

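The test of neighbouring IDs and that of a lag were chosen after the result was seen, as were the set tests.

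Some features were called in both tissues. Bo6g094710 fell in starved roots on day 1 and rose on days 3 and 6, by log2 fold changes of -2.45, 3.67 and 4.31 (limma, adjusted p = 0.00527, 0.000105 and 5.07e-06), and rose in leaves on day 6 by 0.94 (limma, adjusted p = 0.0197). Bo7g114390 fell in roots on all 3 days, by -0.93, -1.74 and -2.02 (limma, adjusted p = 0.00446, 6.15e-06 and 2.27e-07). Bo9g002210, listed at 0 in control roots, held 0.194, 13.1, 13.1 and 9.11 TPM in starved roots a to d on day 1, and 0.0445, 3.07, 0.643 and 3.06 TPM on day 6.

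The rises of day 6 in roots included 238 pairs of features with neighbouring ID numbers, against a mean of 140.0 and a highest value of 169 in 1000 shuffles of the calls. Copies of near-equal length that share reads were excluded as the whole source of the excess, as 2.10% of the pairs had the same coding length and 188 pairs differed in it by over 10%, still above the highest shuffle of all pairs. Day 3 gave 60 pairs among the rises (highest shuffle 44) and 69 among the falls (44), and leaves on day 6 gave 36 among the rises (28) and 4 among the falls (11). Roots on day 1 gave 59 among the rises (46) and 68 among the falls (54), and the root falls of day 6 gave 138 (103). Pairs that differed in length by over 10% numbered 45 and 52 in roots on day 1 and 28 among the leaf rises, not above the highest shuffle. Near-equal copies were therefore not excluded there. Such pairs numbered 46 and 48 on day 3 and 108 among the root falls of day 6, above it. That neighbouring genes rise together is a hypothesis that may account for the pairs among the rises of day 6 in roots. Such copies as a part of the excess, and related copies that differ more in length, stay open, as sequences were not used here.

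Starved roots might lag behind the change of control roots with time. The 1171 features that fell with time in controls had a median log2 fold change of 0.25 in starved roots on day 3, with 883 higher, but the set did not pass with an estimated correlation (limma camera, adjusted p = 0.0653), nor did the 668 that rose (median -0.14, adjusted p = 0.409). The hypothesis stays open, and the change with time in control roots is itself not told from chance by other splits of the samples.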
